A study of Mus musculus with 10 samples.

How the data were processed

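T cell receptor transcripts were sequenced from T cells sorted from mouse ear skin and peripheral lymph node. Per the labels' protocols, RNA of sorted cells was copied by 5′ RACE, the Tcrb or Tcrg transcripts were amplified by PCR, and the indexed products were sequenced on an Illumina MiSeq. Each of the 10 samples was a pool of cells from 5 to 18 animals, so each library is 1 pool and no value per animal exists. The labels name no molecular identifiers. The aligner, clonotype caller, error correction, segment reference and genome build were not given in the sources used here.

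The deposited tables list 1 clonotype per line, and per the file headers their main value is a read count per clonotype. The authors' second value is the fraction of the library's reads, which equalled the count divided by the library total. The files also give the V, D and J segment and the position in the CDR3 (complementarity-determining region 3, the junction that contacts antigen) where each segment ends or starts. A clonotype was a V segment, a J segment and a nucleotide CDR3 sequence. Every listed clonotype was in frame, had no stop codon and belonged to the library's own locus, so 0 were removed by the filter on these properties.

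The TRB libraries held between 31823 and 189162 reads. The 5 bulk Tcrd-/- skin libraries held between 41602 and 52910 reads. A count of 0 allowed a share of up to 0.00943% of reads in the shallowest TRB library and up to 0.00159% in the deepest, taking 3 counts as the upper limit. PCR reads without molecular identifiers are not independent molecules, so all 95% intervals and these limits cover counting error only.

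Samples were grouped by their labels. The replicated comparison was the epidermal Tcrd-/- group (n = 3) against the bulk dermal Tcrd-/- group (n = 2). WT dermis, Tcrd-/- lymph node and both CD103 sorts had 1 library each and were described as values. Nothing in the labels says how animals were divided between the pools, so p-values measure the spread between these libraries. The library names in the labels fall into 3 sets: 1 with the lymph node library, dermal Tcrd-/- A and epidermal Tcrd-/- A, 1 with the CD103 sorts and epidermal Tcrd-/- B, and 1 with the WT libraries, dermal Tcrd-/- B and epidermal Tcrd-/- C.

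Per-library measures were the clonotypes expected at 31823 reads (rarefaction), the inverse Simpson index on the log2 scale, the read share of the 10 largest clonotypes, and 5 CDR3 properties averaged over distinct clonotypes. These were length, inserted nucleotides, the share of clonotypes with no inserted nucleotide, the share with a cysteine after the first residue, and Kyte-Doolittle hydropathy of positions 6 and 7 counted from 1 at the first cysteine. Inserted nucleotides were the CDR3 bases that the deposited positions assigned to no segment. Group means were compared by exact two-sided permutation over all 10 splits of the 5 libraries, where the smallest possible p is 0.2, with Benjamini-Hochberg adjustment over the 8 measures. Overlap was the Morisita-Horn index of clonotypes with the same TRBV, TRBJ and amino acid CDR3, tested one-sided by exact permutation, where the smallest possible p is 0.1.

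Segment usage was tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test on read counts and on clonotype counts per segment with library totals as library sizes, a common dispersion and no TMM factor. Segments needed at least 10 counts over the fitted libraries, and adjusted p (Benjamini-Hochberg) had a threshold of 0.05. The older of the 2 versions of this fit was taken because on simulated data it kept the share of null p-values under 0.05 between 3.58 and 5.005% in the 4 tests, a rate the newer version exceeded for TRBV reads and clonotypes; the choice was made before the real groups were tested. In 100 simulated data sets, counts were drawn from the real means and dispersion, with the expected counts of some segments changed 4-fold or 16-fold. Library sizes were the simulated totals, so the change in share can differ from the stated fold. On TRBV reads (23 segments) the test found 0% of 4-fold and 0% of 16-fold changes. It found 26% and 65% on TRBV clonotypes (21 segments), 5.5% and 15.5% on TRBJ reads (12 segments), and 64.5% and 93.5% on TRBJ clonotypes (11 segments).

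Alternatives fixed before the data were examined were a minimum of 2 reads, leaving out each library, adding both CD103 sorts to the dermal group, TMM factors, DESeq2 1.42.0, no filter on low segments, blocks for replicate letter and library set, amino acid clonotypes, a depth of 1000 reads, read weighting, and other overlap indices. Alternatives added after seeing the data were the removal of clonotypes under 1% of the share that the same nucleotide clonotype had in another library of its set (referred to as trace clonotypes), complete CDR3 sequences only, at least 10 reads, junctions counted from reference sequences, the newer edgeR fit, and overlap over library pairs across sets only. Reference junctions used GENCODE M21 (GRCm38) V, D and J sequences, required 6 matching bases at each end, and passed 1 mismatch followed by 4 matching bases. All 38 TRBV and TRBJ names in the files matched this annotation. Tables were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

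The rule for named items, set before the data were examined, took segments past the threshold, the 5 TRBV segments with the largest mean read share in each group, fixed lists of segments, every TRGV segment, and the 3 largest clonotypes of each library with those recurring between libraries. The fixed lists were TRBV13-2, TRBV29 and TRBV1 (associated with invariant NKT cells), TRBV19 and TRBV13-3 (associated with MAIT cells), TRBV12-1, TRBV12-2, TRBV31 and TRBV13-1 (other common families), and the TRBJ1 and TRBJ2 clusters.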

Results

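Tcrd-/- mice lack the T cell receptor δ chain and so have no γδ T cells, which in wild-type (WT) mice include the dendritic epidermal T cells and many dermal T cells. The series asked which αβ T cells occupy these niches in their absence. T cell receptor β (TRB) transcripts were sequenced from epidermal Tcrd-/- cells (3 libraries), bulk dermal Tcrd-/- cells (2 libraries), CD103+ and CD103hi dermal Tcrd-/- cells, Tcrd-/- lymph node cells and WT dermal cells (1 library each). T cell receptor γ (TRG) transcripts were sequenced from WT epidermal γδ T cells (1 library). CD103 is the integrin αE chain found on many epithelial T cells. The Tcrd gene itself was not measured by these libraries. The epidermal Tcrd-/- libraries A, B and C held 46114, 51359 and 43891 reads in 318, 435 and 72 clonotypes. The dermal Tcrd-/- libraries A and B held 52910 and 41602 reads in 235 and 77 clonotypes. The CD103+ and CD103hi libraries held 42849 and 31823 reads in 492 and 457 clonotypes. The lymph node library held 52498 reads in 26693 clonotypes and the WT dermal library 189162 reads in 702.

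The WT epidermal library was dominated by the invariant γ chain of dendritic epidermal T cells. Of its 180315 reads, 90.0% (exact 95% interval 89.9 to 90.2%) carried TRGV5, TRGJ1 and the CDR3 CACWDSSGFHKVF. All TRGV5 clonotypes together made up 99.4% of reads. TRGV4 took 0.273%, TRGV1 0.171% and TRGV2 0.160% of reads. The next largest clonotypes also used TRGV5 and TRGJ1, with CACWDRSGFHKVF at 5.32% and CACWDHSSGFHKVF at 2.11%. In the GRCm38 annotation TRGV5 lies on chromosome 13 from 19192278 to 19192725 and TRGJ1 from 19210343 to 19210402.

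In these libraries, epidermal Tcrd-/- αβ T cells had more β chains without inserted nucleotides than dermal ones. The share of clonotypes with no inserted nucleotide was 43.4% ± 5.10 (SD, n = 3) in epidermis. It was 18.2% ± 0.0821 (SD, n = 2) in dermis, and the point values of the 2 groups did not overlap. The dermal SD came from 2 close values and understates the counting error. Wilson 95% intervals were 13.9 to 23.7% in dermal A and 11.2 to 28.2% in dermal B. They were 40.8 to 51.7%, 41.8 to 51.1% and 27.2 to 49.0% in epidermal A, B and C. The intervals of dermal B and epidermal C therefore overlapped. By reads the share was 60.3% ± 7.81 (SD, n = 3) in epidermis, and 23.1 and 8.88% in dermal A and B. The exact permutation test of the clonotype shares gave p = 0.2, the smallest this design allows, and 0.8 after adjustment over 8 measures. The difference was 27.9 percentage points within the library set holding the A libraries and 19.3 within the set holding dermal B and epidermal C. The set of epidermal B held no bulk dermal library.

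The WT dermal library had 20.8% of clonotypes without inserted nucleotides (Wilson 95% interval 18.0 to 24.0%), and the lymph node library 17.4% (17.0 to 17.9%). The CD103hi dermal library had 45.1% (40.6 to 49.7%), and the CD103+ dermal library 31.1% (27.2 to 35.3%). Without its 63 trace clonotypes, most of which it shared with epidermal B of the same library set, the CD103+ library had 27.5%. These single libraries have no replicates. With both CD103 sorts added to the dermal group, the difference was 15.2 percentage points with an exact permutation p = 0.114, under the main difference of 25.1 by more than 1.5 times.

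**Figure D1:**
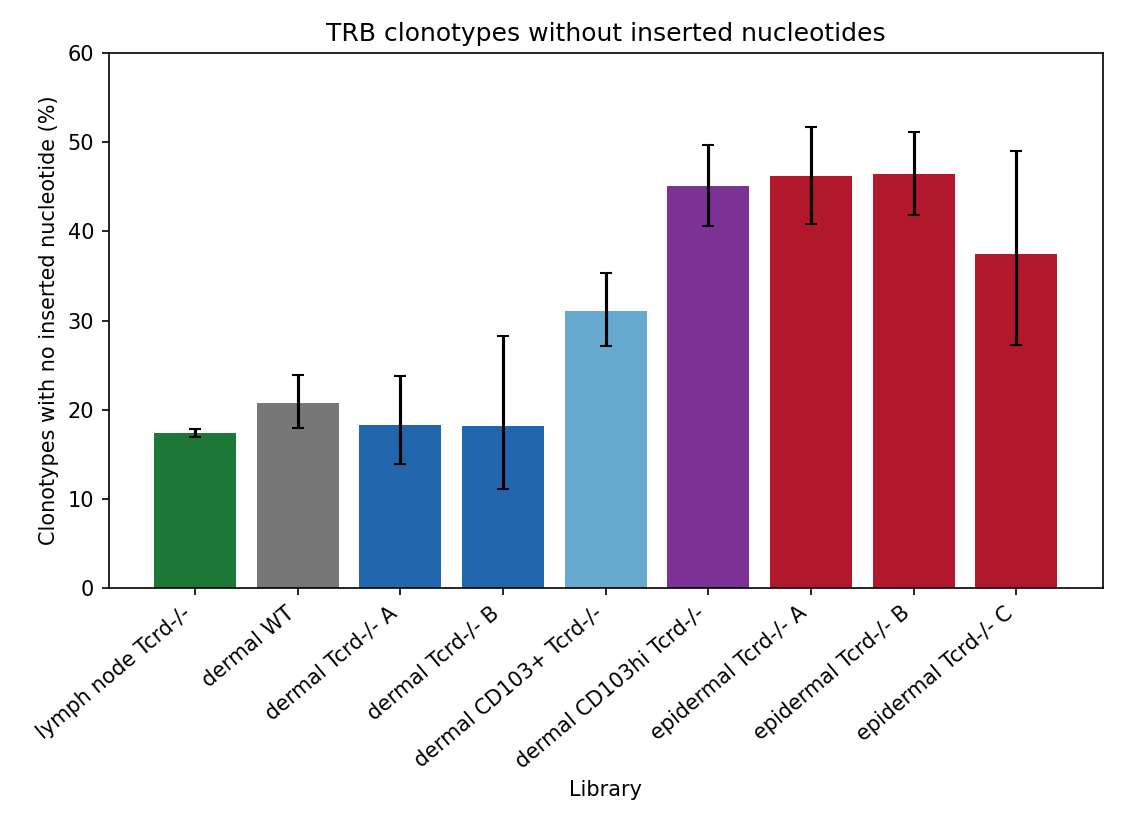
Share of distinct TRB clonotypes with no inserted nucleotide, in percent, for each of the 9 TRB libraries. Bars are single libraries and error bars are Wilson 95% intervals (counting error only). The 3 epidermal libraries lie between 37.5 and 46.4% and the 2 bulk dermal libraries at 18.2 and 18.3%.

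Mean CDR3 length was also lower in each of the 3 epidermal libraries than in both dermal ones. Mean length was 13.1 ± 0.0596 amino acids (SD, n = 3) in epidermis and 13.9 ± 0.131 (SD, n = 2) in dermis, with no overlap and an exact permutation p = 0.2 (0.8 adjusted). The differences within the library sets were -0.873 and -0.746 amino acids. The main difference was -0.839, against -0.550 with both CD103 sorts added to the dermal group (exact permutation p = 0.0571), -1.26 by reads and -1.41 among clonotypes with at least 10 reads. Single CD103hi and CD103+ libraries had means of 13.2 and 13.5. Mean inserted nucleotides were 2.13 ± 0.548 (SD, n = 3) and 3.24 ± 1.04 (SD, n = 2), and these groups overlapped (exact permutation p = 0.4). This difference of -1.11 depended on which dermal library was kept, being -0.376 without dermal A, -1.85 without dermal B and -0.487 with both CD103 sorts added. It was -1.87 by reads, -1.97 among clonotypes with at least 10 reads and -1.74 with junctions counted from reference sequences, and in these 3 the groups did not overlap (exact permutation p = 0.2 each). A cysteine after the first residue occurred in 8.67% ± 3.25 (SD, n = 3) of epidermal and 13.6% ± 8.36 (SD, n = 2) of dermal clonotypes (exact permutation p = 0.6). This difference was within the spread of the libraries. The count includes the cysteine in the CTCS start of the TRBV1 clonotypes among the largest, so it partly follows TRBV1 usage. TRBV1 took 5.53 and 13.0% of clonotypes in dermal A and B, where 7.66 and 19.5% had such a cysteine. The measure therefore cannot be read as the interior cysteines common in unconventional αβ T cells of the gut epithelium. The cysteine difference was -4.90 percentage points, 1.01 in the other direction without dermal B, -10.8 without dermal A, -3.08 without epidermal A and -7.77 by reads. Hydropathy of CDR3 positions 6 and 7 was -1.01 ± 0.141 (SD, n = 3) and -1.18 ± 0.258 (SD, n = 2), with an exact permutation p = 0.4. The hydropathy difference of 0.174 turned to -0.228 by reads and to -0.00889 without dermal B. It was 0.357 without dermal A and 0.106 without trace clonotypes.

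TRBV13-3 was the largest segment of the bulk dermal Tcrd-/- libraries. It took 44.6% of reads in dermal A and 36.5% in dermal B, against 25.0% in WT dermis, 12.4% in the CD103+ and 7.69% in the CD103hi dermal library, and 12.3% in lymph node. By distinct clonotypes it took 22.1 and 15.6% in dermal A and B and 15.5% in WT dermis, so dermal B was like WT dermis. In epidermis its read share was 11.1% ± 9.82 (SD, n = 3), with single libraries at 3.69, 22.3 and 7.43%. The next 4 dermal segments by mean read share were TRBV1 (6.29 and 13.7% in dermal A and B), TRBV13-2 (11.8 and 4.63%), TRBV26 (1.57 and 9.94%) and TRBV5 (4.69 and 6.53%), so the place of TRBV26 rested on dermal B. Epidermal reads were led by TRBV13-2 at 16.3% ± 4.29 (SD, n = 3), TRBV15 at 13.5% ± 13.3, TRBV13-3, TRBV16 at 8.74% ± 4.44 and TRBV12-2 at 8.54% ± 8.96 (18.8, 4.65 and 2.18% in epidermal A, B and C). TRBV15 took 28.1% of epidermal C, 10.4% of epidermal A and 2.02% of epidermal B, and 0.0265% of dermal reads on average.

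No TRBV segment passed the edgeR test, by reads (0 of 23, 4 at an unadjusted p under 0.05) or by clonotypes (0 of 21, 1 at an unadjusted p under 0.05). DESeq2 called 4 TRBV segments by reads (TRBV2 and TRBV15 higher in epidermis, TRBV9 and TRBV23 lower) and 0 by clonotypes. The 2 lower calls rested on dermal A alone, where TRBV9 took 2.17% and TRBV23 0.524% of reads, since neither was found in dermal B. TRBV9 is a pseudogene in the GRCm38 annotation, and its assignment was not tested. TRBV2 was not found in dermal A, dermal B or epidermal C. Simulated 16-fold changes in TRBV reads were not found by the edgeR test at this dispersion, so a count of 0 does not show like usage. Of the invariant NKT-associated list, none of TRBV13-2, TRBV29 and TRBV1 passed. TRBV1 had 1.25, 7.14 and 0.00911% of reads in epidermal A, B and C, against the dermal shares above (edgeR adjusted p = 0.805). Of the MAIT-associated list, neither TRBV19 (edgeR adjusted p = 0.756) nor TRBV13-3 (0.689) passed by reads, and TRBV13-3 had an edgeR adjusted p of 0.648 by clonotypes. None of TRBV12-1, TRBV12-2, TRBV31 and TRBV13-1 passed either. These segments lie on chromosome 6 of GRCm38, with TRBV13-3 from 41130147 to 41130585 and TRBV31 from 41557691 to 41558452.

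**Figure D2:**
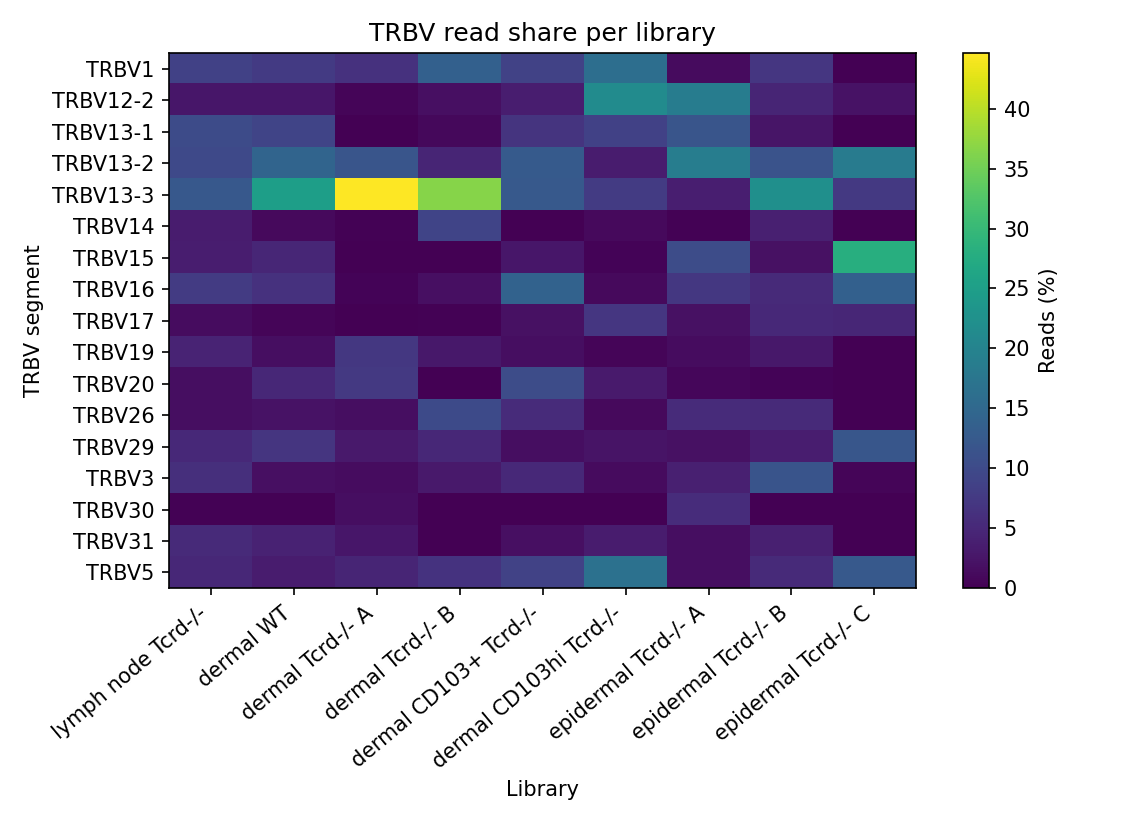
Read share in percent of each TRBV segment that reached 5% in at least 1 TRB library (17 segments, rows) in the 9 TRB libraries (columns). TRBV13-3 is highest in dermal A and B, at 44.6 and 36.5%.

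TRBJ usage by clonotypes was close to the threshold for 2 segments in the main fit. TRBJ1-4 made up 1.81% ± 1.21 (SD, n = 3) of epidermal and 4.92% ± 3.28 (SD, n = 2) of dermal clonotypes. These groups overlapped, with 7.23% in dermal A but 2.60% in dermal B, which lay under the 2.78% of epidermal C from the same library set. TRBJ2-3 made up 7.07% ± 3.61 (SD, n = 3) and 15.9% ± 1.41 (SD, n = 2). Both had an edgeR adjusted p of 0.0561 by clonotypes, so 0 of 11 TRBJ segments passed, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. The newer version of the edgeR fit called both, with a lowest adjusted p of 0.0442, and was 1 of 4 alternatives that called TRBJ segments by clonotypes. Other alternatives moved away from the threshold. The lowest edgeR adjusted p was 0.396 without epidermal B, 0.140 without epidermal A, 0.179 with the replicate block and 0.124 with library set as a block. Without epidermal C the lowest edgeR adjusted p was 0.0595, near that of the main fit. By reads both segments had an edgeR adjusted p of 0.836 in the main fit. By reads 0 of 12 passed, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2, and 1 (TRBJ1-6) passed without epidermal C. That segment took only 0.121, 0.0643 and 0% of reads in epidermal A, B and C and was not found in dermal A or B. In the CD103+ and CD103hi dermal libraries it took 0.0163 and 0.471%. The TRBJ1 cluster took 24.8% ± 4.15 (SD, n = 3) of epidermal and 24.4% ± 3.35 (SD, n = 2) of dermal clonotypes (exact permutation p = 1), the rest being TRBJ2.

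The 10 largest clonotypes held a higher read share in each skin library than in the lymph node library, and that share varied widely among skin libraries. They held 48.8% ± 31.4 (SD, n = 3) of epidermal and 52.9% ± 13.6 (SD, n = 2) of dermal Tcrd-/- reads, against 15.1% in WT dermis and 0.539% in lymph node. The CD103+ and CD103hi libraries had 25.4 and 29.8%. Epidermal C (84.4%) and dermal B (62.6%) had the highest shares and the fewest clonotypes, 72 and 77, and belong to 1 library set. These shares were not adjusted for the number of cells in each library, and equal read depth does not equalise cells. They therefore cannot be read as clonality alone. Epidermal libraries ranged from 24.7% in B to 84.4% in C, so the epidermal and dermal groups overlapped (exact permutation p = 1), and the sign of the difference turned without epidermal A (1.60), epidermal B (7.97) or dermal B (5.55). It was -4.10 in the main comparison, -21.9 without epidermal C and -13.8 without dermal A. At 31823 reads, 232 ± 152 clonotypes (SD, n = 3) were expected in epidermis and 132 ± 87.6 (SD, n = 2) in dermis (exact permutation p = 0.6). The difference of 101 was 38.6 without dermal B, 162.5 without dermal A, 40.4 without epidermal B and 186 without epidermal C, and it turned to -54.5 with both CD103 sorts added. WT dermis gave 510 and lymph node 19977. The inverse Simpson index was 45.1 ± 34.8 (SD, n = 3) in epidermis and 23.6 ± 5.89 (SD, n = 2) in dermis (exact permutation p = 0.8 on the log2 scale), and its log2 difference of 0.508 was -0.12 without epidermal B, 1.37 without epidermal C, 0.765 without dermal A, 0.274 without epidermal A and 0.251 without dermal B.

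The largest clonotypes differed between libraries. Epidermal C was led by TRBV15, TRBJ1-1 and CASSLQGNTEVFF at 21.8% of reads, with no inserted nucleotide, followed by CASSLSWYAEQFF (TRBV29) at 12.0% and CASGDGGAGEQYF (TRBV13-2) at 9.87%. Epidermal A was led by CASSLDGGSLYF and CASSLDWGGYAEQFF (both TRBV12-2) at 4.94 and 4.80% and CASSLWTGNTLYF (TRBV26) at 4.53%. Epidermal B was led by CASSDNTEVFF (TRBV13-3) at 3.40%, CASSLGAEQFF (TRBV26) at 2.95% and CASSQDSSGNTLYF (TRBV5) at 2.69%. All 3 leading clonotypes of dermal A used TRBV13-3, with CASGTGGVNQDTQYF at 13.5%, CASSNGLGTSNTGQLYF at 4.80% and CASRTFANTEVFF at 4.73%. Dermal B was led by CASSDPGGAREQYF (TRBV13-3) at 10.7%, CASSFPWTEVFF (TRBV14) at 9.20% and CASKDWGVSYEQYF (TRBV13-3) at 8.44%.

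The CD103hi library was led by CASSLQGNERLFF (TRBV12-2) at 7.04%, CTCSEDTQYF (TRBV1) at 4.36% and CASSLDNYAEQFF (TRBV12-2) at 4.14%. The CD103+ library was led by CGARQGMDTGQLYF (TRBV20) at 5.51%, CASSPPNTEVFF (TRBV16) at 3.91% and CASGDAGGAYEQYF (TRBV13-2) at 2.97%. WT dermis was led by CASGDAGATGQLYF (TRBV13-2) at 2.66%, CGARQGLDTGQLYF (TRBV20) at 2.27% and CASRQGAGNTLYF (TRBV13-3) at 1.94%. In the lymph node library the 2 largest entries were incomplete sequences, YAEQFF at 0.250% and GAEQFF at 0.0514%, and the next was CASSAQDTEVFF (TRBV13-1) at 0.0495%.

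Few clonotypes were shared between skin libraries of different sets (0 to 6 amino acid clonotypes per pair). Of the 10 largest clonotypes of each TRB library, 0 were among the 10 largest of another. The only amino acid clonotype in all 3 epidermal libraries was the incomplete GAEQFF, assigned to TRBV8, which is annotated as a pseudogene. GAEQFF was also listed in WT dermis (15 reads), lymph node (27 reads) and dermal B (1 read). The mean Morisita-Horn index was 1.19e-04 over the 3 epidermal pairs and 1.60e-04 over the 6 epidermal-dermal pairs (one-sided exact permutation p = 0.4), and the sign of this difference turned without trace clonotypes (7.27e-05), without epidermal C (1.19e-04) and without dermal A (1.09e-04). It was -4.10e-05 in the main comparison, -6.28e-06 without epidermal A, -2.36e-04 without epidermal B and -1.91e-04 without dermal B. With both CD103 sorts added it was -3.29e-04, for nucleotide clonotypes -1.42e-04 and with at least 2 reads -1.35e-05. All 3 epidermal pairs crossed library sets, whereas 2 of the 6 epidermal-dermal pairs did not, and these 2 had indices of 9.29e-04 and 2.90e-05. Over pairs across sets only, the difference also turned (1.19e-04, one-sided exact permutation p = 0.2), and it rested on epidermal A and B (3.52e-04). The test of all pairs therefore does not separate tissue from library set. Over pairs of skin libraries, the median number of shared amino acid clonotypes was 29 within a library set (7 pairs) and 1 between sets (21 pairs). Dermal A and epidermal A, of 1 set, shared 29, which held 2.21% of dermal A and 39.1% of epidermal A reads, and 21 of the 27 shared nucleotide clonotypes had under 1% of the share in the other library. CD103+ and CD103hi cells shared 32 amino acid clonotypes, which held 18.4% of CD103+ and 15.1% of CD103hi reads. The CD103+ library shared more, 81, with epidermal B, which held 6.86% of CD103+ and 66.5% of epidermal B reads. All 3 libraries belong to 1 set. Of the nucleotide clonotypes shared, 64 of 80 with epidermal B and 7 of 30 with CD103hi had under 1% of the share in the other library. The mean index of CD103hi with the epidermal libraries minus that of CD103+ was -1.14e-04, and it turned to 5.26e-04 without trace clonotypes.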

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

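Of the tests in this part, those of the reference junctions and of trace sharing were chosen after the results were seen. Some clonotypes were listed with TRBD2 and a TRBJ1 segment. TRBD2 lies downstream of the TRBJ1 cluster (chromosome 6, 41542163 to 41542176, GRCm38), so the deletion that usually joins segments would not pair them. Among TRBJ1 clonotypes with an assigned D segment, 14.3% were listed with TRBD2 in WT dermis, 8.33% in the CD103+ library and 8.02% in lymph node, above what a count of 0 allows. In epidermal A, B and C the shares were 2.08, 5.71 and 0%, in dermal A and B 7.5 and 0%, and in CD103hi 3.53%. None of these was above that limit for its library. Whether these D names are right was not tested. No comparison used the names, but the positions of these D segments entered the counts of inserted nucleotides. Junctions counted from reference sequences did not pair TRBD2 with TRBJ1.

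The high share of epidermal clonotypes without inserted nucleotides was set against 3 explanations. These were segment usage, selection for short CDR3 sequences and D segments missed in the deposited positions, of which only the last is technical. At lymph node rates for each pair of V and J segments, segment usage alone gave a difference of 0.356 percentage points, against 25.1 observed. At lymph node rates for each CDR3 length, 23.6 points were left over, with an epidermal excess of 23.9 ± 5.35 (SD, n = 3) and dermal A and B values of 1.39 and -0.732. The excess was not confined to epidermis, being 25.9 in the CD103hi and 12.7 in the CD103+ dermal library. With junctions counted from reference sequences the difference was 27.1 points. These values argue against segment usage, selection for short CDR3 sequences and missed D segments as the whole cause. A hypothesis that stays open is that the epidermal and CD103hi cells may carry receptors rearranged while little nucleotide addition takes place, as before birth; no sample of known age of origin tests it, and the sort gates of the groups also differed.

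Nucleotide clonotypes were shared mostly within library sets. Of those shared by skin libraries of a set, 62.5% had under 1% of the share they had in the other library, against 6.25% of those shared across sets. The pairs differed. CD103+ and epidermal B gave 64 of the 125 such clonotypes (64 of 80 shared). The counts were 21 of 27 for dermal A and epidermal A, 18 of 32 for WT dermis and epidermal C, and 8 of 10 for CD103hi and epidermal B. They were 7 of 30 for CD103+ and CD103hi, 4 of 12 for WT dermis and dermal B, and 3 of 9 for dermal B and epidermal C. Carry-over of reads between libraries prepared together could give such low shares. Shared animals within a set could also give sharing, and the labels do not say how animals were assigned, so that biological explanation was not tested.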

How the results depend on the processing

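The added alternatives (trace clonotypes removed, complete CDR3 only, at least 10 reads, reference junctions, newer edgeR fit, overlap across library sets only) were chosen after seeing the data. Of 188 alternative values, 18 turned direction and 6 called segments where the main fit called none. The others kept their direction and side of the threshold, with 160 classed as the same and 4 as moved. For differences between groups, the class of the same includes values that kept direction but changed size. The Morisita-Horn difference, for example, was -4.10e-05 in the main comparison and -3.29e-04 with both CD103 sorts added. Each block left out an epidermal library, so for per-library measures it repeats a leave-out value within the total of 188. The exact tests over 5 libraries cannot reach 0.05, nor can the two-sided ones over 7, so their p-values say nothing of stability. The epidermal excess of clonotypes without insertions and the shorter epidermal CDR3 kept their direction in every alternative run, but not their size. Including non-productive clonotypes changed nothing, since none were listed. Where 1 dermal library was left, it was assumed to vary like the epidermal ones. For other results the cause of a change was not tested.

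With both CD103 sorts added, the expected clonotype difference was -54.5, the log2 Simpson difference -0.23, the top 10 difference 8.55 points, and 1 TRBJ segment passed by clonotypes. With library set as a block, which leaves out epidermal B, the Simpson and top 10 differences were -0.12 and 7.97. These are the values without epidermal B. Leaving out 1 library gave ranges of -0.12 to 1.37 (Simpson), -21.9 to 7.97 (top 10), -10.8 to 1.01 (cysteine), -0.00889 to 0.357 (hydropathy), -2.36e-04 to 1.19e-04 (Morisita-Horn) and 0 to 1 (TRBJ by reads). Read weighting turned hydropathy to -0.228. DESeq2 called 4 TRBV segments by reads. TRBJ segments by clonotypes numbered 2 without trace clonotypes, 2 without the low filter and 2 with the newer edgeR fit. The Morisita-Horn difference was 7.27e-05 without trace clonotypes and 1.19e-04 across library sets only. The CD103hi minus CD103+ overlap was 6.14e-05 with at least 2 reads, 5.26e-04 without trace clonotypes and -0.0269 as Jaccard. The largest clonotype alone gave 9.44 points (dermal Tcrd-/- minus WT) and 10.6 points (skin minus lymph node). Any TRGV5-TRGJ1 CDR3 gave 99.3%.

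Both A libraries belong to 1 library set and the B libraries to different ones, so letters pair the samples by a label only for A. Correlations of same-letter deviations ran from -0.603 to 0.348 over the segment tables. With 2 dermal libraries, their deviations from the group mean mirror each other. The correlations for A and B are therefore tied, and they cannot show whether letters pair the samples. The replicate block leaves out epidermal C, so its no-insertion difference of 28.1 points is the value without that library. With this block 0 segments passed in all 4 tests, and no call changed.

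With 3 epidermal against 4 dermal libraries, real counts of 0 for TRBV reads, TRBV clonotypes and TRBJ reads are reached by every split (35 of 35) by construction, with at most 1 in another split, which says nothing about chance. The count of 1 for TRBJ clonotypes was reached by 5 of 35, with at most 1 in another split, so chance cannot be excluded. Depth limits shares below 0.00943% of reads in the shallowest TRB library.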

Other observations

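The second largest γ chain sequence of WT epidermal T cells, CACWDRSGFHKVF, differed from the canonical CDR3 by A16C, counted from 1 at the 5′ end of the CDR3 nucleotide sequence (canonical base first). It was the only 1 of 117 possible single-base neighbours listed, at 5.32% of reads (exact 95% interval 5.22 to 5.43%). No neighbour with 2 differences was listed, but 23 sequences of the same length had 3 or more, 15 of them with TRGV5. The error correction behind the deposited data is not known, so this lack of near neighbours cannot be read as a trait of the cells.

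Among the 10 largest amino acid clonotypes, some had at least 1 nucleotide version with no inserted nucleotide. These numbered 7 in epidermal A, 4 in epidermal B and 5 in epidermal C, against 3 in dermal A and 1 in dermal B. The CD103hi library had 5, the CD103+ library 4, and WT dermis and lymph node 3 each, of which 2 in lymph node were the incomplete YAEQFF and GAEQFF. Among clonotypes with at least 10 reads, the share without insertions was 63.3, 54.4 and 69.2% in epidermal A, B and C, and 14.6 and 11.9% in dermal A and B.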
